A study of Mus musculus with 16 samples.

How the data were processed

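RNA was measured in the distal stump of the mouse sciatic nerve with an Affymetrix mouse whole-genome array. The mice came from C57BL/6 and from C57BL/6 OlaHsd-Wlds, called WldS here, with 56 per strain and an age of 8 to 12 weeks per the labels. The left nerve was crushed at mid-thigh in all but the uninjured mice. A 4 mm segment, from 1 to 5 mm distal to the lesion, was taken at day 0 (uninjured), 3, 7 or 14, the stumps of a group were pooled before RNA extraction, and 10 µg of total RNA went into the labelling. There were 8 groups (2 strains at 4 time points) with 2 arrays each, which the labels call biological replicates. They are taken here as separate pools, so n = 2 pools per group throughout. The number of mice behind each pool is not stated, nor is whether the 2 arrays of a group came from separate dissections.

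The deposited values are log2 probe set signals that the authors had normalized between arrays. GCOS 1.4, RMA, limma and Partek are named without a role, per the submitters' processing notes. All arrays had nearly equal quantiles, with medians between 6.42 and 6.49. Array data carry no count depth, so the number of arrays limits the precision.

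The table held 45101 probe sets, of which 64 were control probe sets and were left out of the gene tests. With the symbols of the platform's probe table, 34945 probe sets had 1 gene symbol, 932 had several and 9160 had none listed, and only the first kind was used at gene level. A gene took the value of its probe set with the highest mean over the 16 arrays, which gave 18193 genes. Genes whose probe set mean lay below the 30th percentile of all probe sets other than controls (log2 5.37) were left out as dim, and 14545 genes were tested. The reference gene table was used only for which genes neighbour Nmnat1, and no coordinates were used.

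Group means were fitted with limma 3.58.1 in R 4.3.3 to all 16 arrays, with 8 residual degrees of freedom and 5.82 prior degrees of freedom, and contrasts were tested two-sided with limma's moderated statistic. The p-values were adjusted by the Benjamini-Hochberg method within each contrast over all genes tested, and a gene was called at adjusted p below 0.05. There were 14 contrasts. These were each later day against day 0 in each strain, WldS against C57BL/6 at each of the 4 time points and over their mean, and the interaction at each later day, which is the WldS change from day 0 minus the C57BL/6 change. Values after ± are standard errors for differences and standard deviations for group means. All p-values reflect the spread between pools, not between mice.

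Lists of genes were tested with limma's camera with a preset inter-gene correlation of 0.01, adjusted over the 29 lists within a contrast, and again with an estimated correlation. Members past the threshold were counted with p adjusted over all genes and adjusted over the list alone. Calls of lists are given with the preset correlation, and the adjusted p with the estimated correlation follows where it ends the call. The 29 lists, the contrasts, the tests, the filters and the alternatives were fixed before the data were examined, except 2 alternatives added later. These leave out 2 arrays with a high 3'/5' index or take that index as a covariate. The index is the mean over Actb and Gapdh of the log2 signal of the 3' control probe set minus that of the 5' one. Some members of the lists are not reported here. The marker lists for plasma cells, B cells and lymphatic vessels were chosen after the strain differences had been seen.

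The text names, per contrast, genes from the 5 with the largest rise and the 5 with the largest fall among called genes, passing over clone names and, for a contrast of 2 groups, genes whose arrays overlapped between groups. It also names up to 4 called members of a described list with the largest change, and every measured gene of the list of the WldS locus and strain genes. Any other gene was chosen after its values were seen, and is marked so.

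Agreement between strains was described by the genes called in both in the same direction, beside the number independent lists would share (the product of both counts over the genes tested), and by correlations across genes, which are not independent replicates. Each strain had its own day 0 arrays, so these comparisons shared no array. For the strain contrast over all time points, strain labels were also shuffled within time points in 100 splits, the real one included.

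The fit was tested on simulated values drawn from the real gene means and spreads of the 14545 genes, with 200 of them changed in the WldS day 3 group. For WldS day 3 against day 0, changes of 0.5, 1 and 2 on the log2 scale were called in 28%, 98% and 100% of 50 genes each. For the interaction at day 3 the shares were 8%, 68% and 100%. Of the unchanged genes, 9 were called for WldS day 3 against day 0. In the unchanged comparison of C57BL/6 day 3 with day 0, limma called 0 genes (715 at an unadjusted p below 0.05) and camera 0 of 29 lists (2 unadjusted). The simulated genes varied independently of each other, and each gene had the same spread in all groups. The run therefore cannot show how often lists are called in error where genes vary together. Nor can it show how often genes are called in error where groups differ in spread.

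Alternatives changed 1 choice at a time. They were no dim filter, a filter at the 50th percentile, every probe set tested singly, the mean of all probe sets of a gene, 3 further normalizations (median centring, quantile normalization and cyclic loess), limma with an intensity trend and robust setting, only the arrays of the groups compared, a fold threshold of 2, the replicate number as a block, and leaving out each array in turn. Tables and figures were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.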

Results

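The data were log2 expression values from 16 arrays of pooled sciatic nerve distal stumps, taken from C57BL/6 mice and from WldS mice, a strain whose cut axons degenerate slowly, before injury and 3, 7 and 14 days after a nerve crush. Each of the 8 groups had 2 arrays, taken as separate pools. All p-values below reflect the spread between pools. Differences from a group mean below the dim filter (log2 5.37) are lower bounds, as for Gdnf, Arg1, Chil3, Wif1 and Clca3a2 in uninjured nerves. The median standard deviation between the pools of a group ran from 0.061 (C57BL/6 day 7) to 0.145 (WldS day 0) on the log2 scale. The first principal component held 51.1% of the variance and the second 20.6%. The 3'/5' index of the control probe sets, a sign of RNA quality, was 3.81 in WldS day 0 replicate 1 and 3.23 in WldS day 14 replicate 2, against 2.29 and 2.36 in the C57BL/6 day 0 arrays.

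**Figure D1:**
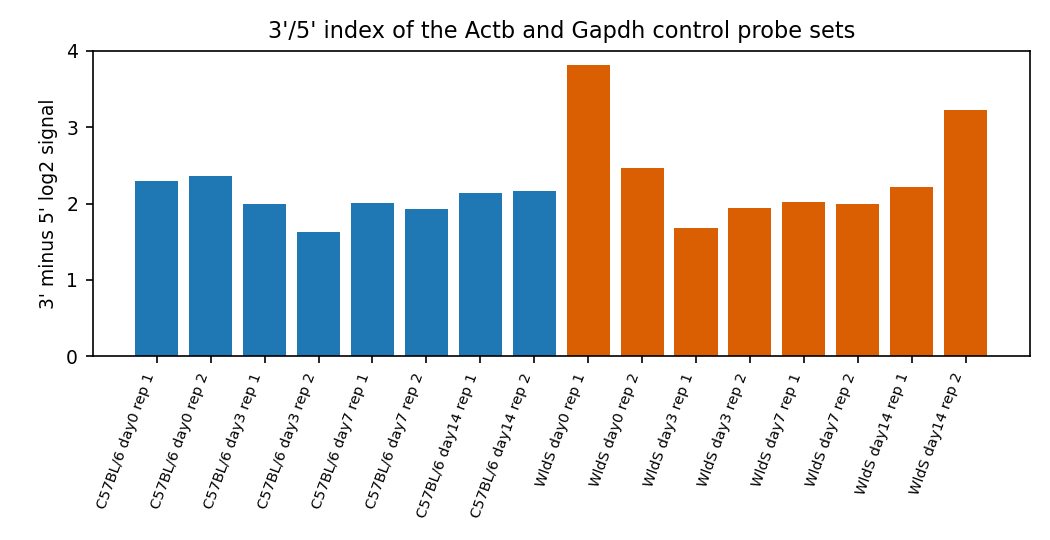
Bars give the 3'/5' index of each array (mean over Actb and Gapdh of the 3' minus the 5' log2 signal), blue for C57BL/6 and orange for WldS. WldS day 0 replicate 1 (3.81) and WldS day 14 replicate 2 (3.23) had the highest values.

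The first question was whether the arrays carried the genotype of each strain. Nmnat1, an NAD-synthesizing enzyme whose coding sequence is part of the WldS fusion gene, was higher in WldS at every time point, at 9.19 ± 0.23 against 6.17 ± 0.23 at day 0 (log2 signal, SD, n = 2), a difference of 3.01 ± 0.16 (limma adjusted p = 1.59e-07). Its differences at day 3, 7 and 14 were 2.69, 3.09 and 3.40, and all 8 WldS arrays lay above all 8 C57BL/6 arrays. Rbp7, a retinol-binding protein gene that lies between Ube4b and Nmnat1 in the reference gene order, was 0.61 ± 0.08 higher over the mean of the time points (adjusted p = 0.000144). Ube4b, whose 5' end supplies the start of the fusion protein, did not pass at any time point, with a mean difference of -0.10 ± 0.07 (adjusted p = 0.313), and the position of its probe sets relative to the fused part was not analysed here. Mmrn1, a multimerin gene, was 2.02 ± 0.26 higher in WldS over all time points (adjusted p = 0.000103), although it had entered the list as a gene deleted in the OlaHsd background. Its C57BL/6 means lay between 5.44 and 5.66, near the dim filter, and the WldS pools differed among themselves by more (6.92 ± 0.82 at day 3 and 8.07 ± 1.28 at day 7).

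Pttg1, which encodes securin, was at 13.11 ± 0.00 in uninjured C57BL/6 nerves and at 10.34 ± 0.15 in uninjured WldS nerves, a difference of -2.77 ± 0.11 (limma adjusted p = 1.09e-08) that its 2 other probe sets shared (-1.41 and -2.75). After injury Pttg1 rose in WldS by 2.28, 1.78 and 1.58 at day 3, 7 and 14 and fell by 0.72, 0.63 and 0.57 in C57BL/6, and its interaction passed at each day (3.00, 2.41 and 2.14). Of its other probe sets, 1 had interactions of 2.63, 2.23 and 1.67 and the other of only 1.17, 0.72 and 0.26, with a change of 0.25 in C57BL/6 at day 14. With the mean of the probe sets the interaction still passed, at 2.26, 1.79 and 1.36. Edil3, an extracellular matrix gene, was lower in WldS by -1.50 ± 0.19 at day 7 (adjusted p = 0.00016), and its interaction at that day did not pass (adjusted p = 0.0502). The other Edil3 probe sets, all dimmer than the filter on average, differed by -0.50 to 0.01 at day 7. Nnt, the mitochondrial transhydrogenase gene, differed by 0.13 ± 0.08 over all time points (adjusted p = 0.277), and Erdr1 by -0.25 ± 0.10 (adjusted p = 0.0964). The 4 sex genes tested did not pass as a list in any contrast between the strains or interaction (camera adjusted p from 0.830 to 0.987). This test is directional, so opposite changes of its members could cancel, and it cannot exclude a difference in sex between the pools.

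**Figure D2:**
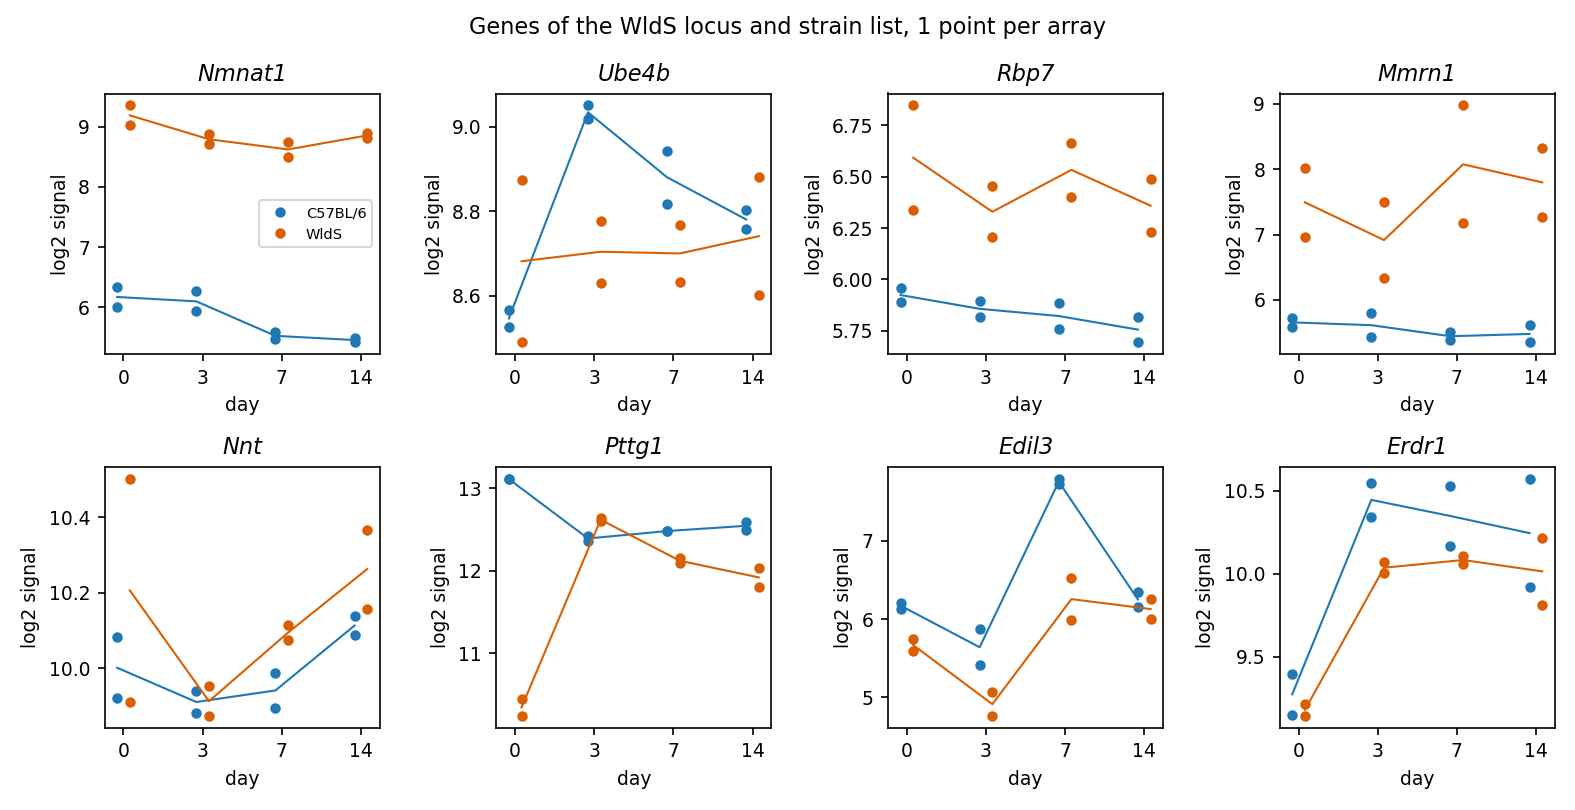
Points are arrays and lines group means (log2 signal against day after crush), blue for C57BL/6 and orange for WldS, for the 8 measured genes of the WldS locus and strain list. Nmnat1 was higher in WldS at every time point, and Pttg1 differed most at day 0 (-2.77).

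The second question was how uninjured nerves of the strains differed. Among the genes higher in WldS nerves at day 0 than in C57BL/6 were Jchain, Mageb16, Ighm and Igkv8-30. Jchain, the joining chain of polymeric immunoglobulins, was higher by 3.16 ± 0.50 (limma adjusted p = 0.0189), Ighm, the IgM heavy chain, by 2.75 ± 0.48 (adjusted p = 0.0332) and Igkv8-30, a light chain segment, by 2.61 ± 0.37 (adjusted p = 0.0109) from a C57BL/6 level of 5.13, below the dim filter. For Ighm the next brightest probe set differed by 1.36 and others by less. Mageb16 was at 7.34 ± 0.41 against 4.35 ± 0.06 and remained below the dim filter in all C57BL/6 groups, so its difference was at least 2.99 ± 0.20 (adjusted p = 2.3e-06). Lower in WldS were Pttg1, Them5 (-2.72 ± 0.17, a lower bound in size since WldS lay at 5.49, near the dim filter), Frzb, a secreted Wnt antagonist (-2.00 ± 0.21), Lepr, the leptin receptor (-1.49 ± 0.24), and Lyve1, a hyaluronan receptor of lymphatic vessels and some macrophages (-1.03 ± 0.18). The other 2 Them5 probe sets, both dimmer than the filter on average, differed by -0.02 and -5.34, and the other of Frzb by -1.21. The next brightest probe set differed by -0.32 for Lepr and -0.21 for Lyve1, and the further Lepr probe sets by -1.64 and 0.05. With the mean of all probe sets the calls of Ighm (0.46, adjusted p = 0.163), Lepr (-0.85, adjusted p = 0.122) and Lyve1 (-0.62, adjusted p = 0.202) ended. Markers of B cells and plasma cells chosen after the values were seen were compared over the mean of the time points. Mzb1, a plasma cell chaperone, was higher by 0.35 ± 0.07 (limma adjusted p = 0.00365). Prdm1 was lower (-0.23 ± 0.06, limma adjusted p = 0.0253), and no other of the 9 plasma cell markers passed. Of the B cell markers, Cd79a (0.07 ± 0.07) and Ms4a1 (0.22 ± 0.08) did not pass and lay near the dim filter, and Cd22 was lower (-0.56 ± 0.09).

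In all, 33 of 14545 genes differed at day 0, 12 higher and 21 lower in WldS, and 2549 had an unadjusted p below 0.05. Of the 29 lists, camera called skeletal muscle (median 0.25, adjusted p = 0.000655) and mast cell genes (0.30, adjusted p = 0.00908) higher and extracellular matrix (-0.30, adjusted p = 0.00193) and endothelial genes (-0.22, adjusted p = 0.00751) lower, and each had an adjusted p of 0.578 with an estimated correlation. Adjusted over the list alone, 2 of 10 skeletal muscle genes, 1 of 9 mast cell genes, 3 of 28 matrix genes and 1 of 15 endothelial genes passed. Without both high-index arrays the matrix and endothelial calls ended (adjusted p = 0.2 and 0.117), and the same holds without WldS day 0 replicate 1 alone (0.212 and 0.134), while the mast cell call ended without C57BL/6 day 0 replicate 1 (0.106) or WldS day 0 replicate 2 (0.353), as did the skeletal muscle call without the latter (0.158). The count of genes rested on single arrays. It was 7 without C57BL/6 day 0 replicate 1, 17 without replicate 2, 20 without WldS day 0 replicate 1 and 1791 without WldS day 0 replicate 2, which leaves the high-index array alone in its group. Without both high-index arrays 14 were higher and 9 lower, so the majority direction was not fixed. The calls of Nmnat1, Mageb16, Pttg1, Them5 and Frzb held without each of these, and those of Jchain, Ighm, Igkv8-30, Lepr and Lyve1 ended without either C57BL/6 array or without WldS day 0 replicate 1.

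The third question was what a crush did to the C57BL/6 nerve. At day 3 genes of myelin and of its lipid supply fell and genes of repair Schwann cells, macrophages and dividing cells rose. Of 19 myelin genes, 16 fell and 3 rose (median -2.07, camera adjusted p = 1.04e-10, 0.0594 with an estimated correlation). The largest falls were those of Ncmap, a myelin-associated membrane protein (-5.72 ± 0.20), Fa2h, which makes hydroxylated myelin lipids (-4.95), Ugt8a, which makes galactolipids (-4.24), and Cmtm5 (-4.21). Of 20 cholesterol synthesis genes, 18 fell (median -1.95, adjusted p = 5.61e-13), among them Idi1 (-3.28) and Hsd17b7 (-2.97). Of 20 repair Schwann cell genes, 13 rose and 2 fell (median 1.29, adjusted p = 6.54e-06), led by Gdnf, a neurotrophic factor (5.10 ± 0.17), Shh, a secreted morphogen (4.38), and Btc, an EGF receptor ligand (4.03).

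Also at day 3, 21 of 22 macrophage genes rose (median 1.96, camera adjusted p = 3.11e-13, 0.0540 with an estimated correlation), led by Arg1, an arginine-degrading enzyme (6.12 ± 0.39), and Lgals3 (3.40). All 28 cell cycle genes rose (median 2.89, adjusted p = 2.27e-23), led by Mki67 (5.11 ± 0.17) and Rrm2 (5.08 ± 0.14). Of 23 cytokine and chemokine genes, 17 rose and 1 fell (median 1.06, adjusted p = 1.51e-06), with the monocyte attractant Ccl2 at 3.13. Of 14 immediate early genes 10 rose and 1 fell (median 0.80, adjusted p = 0.000799). Of 11 adipocyte genes, 9 fell (median -1.97, adjusted p = 1.52e-05, 0.256 with an estimated correlation) and of 16 fibroblast and perineurial genes 10 fell and 1, Wif1, rose (4.45, list adjusted p = 0.000819, 0.108 with an estimated correlation). Timp1, an inhibitor of matrix proteases, rose by 5.09 ± 0.15. The calls of the cholesterol synthesis, repair Schwann cell, cell cycle, cytokine and immediate early genes at this day held with an estimated correlation. Adjusted over the list alone, the counts were equal except for adipocyte (11 lower), fibroblast (12 lower) and immediate early genes (11 higher, 2 lower).

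By day 7 the C57BL/6 nerve had its largest fall of cholesterol synthesis genes. Of 20, 17 fell (median -2.56, camera adjusted p = 1.08e-17), and 16 of 19 myelin genes were still lower with 1 higher (median -1.50, adjusted p = 3.71e-11, 0.0705 with an estimated correlation). The myelin gene that rose was Pou3f1, a transcription factor of promyelinating Schwann cells (2.77). Repair Schwann cell genes stayed up (13 higher and 2 lower of 20, median 1.37, adjusted p = 3.35e-08), with Tnc, a matrix glycoprotein, at 4.54 and Sox2, a factor of immature Schwann cells, at 3.29. Phagocytosis and lysosome genes reached 21 higher and 1 lower of 23 (median 1.11, adjusted p = 3.59e-11), and macrophage genes 18 higher and 1 lower of 22 (median 1.60, adjusted p = 2.6e-11, 0.0705 with an estimated correlation). Clca3a2 (5.59 ± 0.24) and Wif1, a Wnt inhibitor (5.48 ± 0.14), rose most, and Fam107a (-6.33 ± 0.25) and Ddn (-5.49 ± 0.18) fell most. All 28 cell cycle genes were higher (median 2.08). Of 28 extracellular matrix genes 18 rose and 1 fell (adjusted p = 3.28e-06, 0.251 with an estimated correlation).

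By day 14 the myelin genes of C57BL/6 no longer stood apart, with 4 higher, 6 lower and 9 of 19 not passing (median -0.10, camera adjusted p = 0.771). Ncmap was back at 11.52 ± 0.37 from 6.91 ± 0.04 at day 3, against 12.63 ± 0.10 before injury. Cholesterol synthesis genes remained lower (16 of 20, median -1.25, adjusted p = 2.22e-10), as repair Schwann cell genes remained higher (13 higher, 3 lower of 20, median 1.19, adjusted p = 2.51e-05). Macrophage genes were higher in 17 and lower in 2 of 22 (adjusted p = 2.22e-10, 0.103 with an estimated correlation). Chil3, a chitinase-like protein of myeloid cells, was the gene that rose most (6.08 ± 0.20, limma adjusted p = 2.69e-10). It and Arg1 had a course of 2 peaks, with Chil3 at 9.52, 5.53 and 11.01 and Arg1 at 11.16, 6.47 and 9.85 on day 3, 7 and 14. Bex1, a small protein of neural tissue, rose by 4.95 ± 0.33. Of 15 endothelial genes 7 were lower (adjusted p = 0.00253, 0.343 with an estimated correlation), and of 28 oxidative phosphorylation genes 13 were lower and 1 higher (adjusted p = 0.00444, 0.472 with an estimated correlation). Axonal neuron genes were lower in 4 and higher in 1 of 11 (adjusted p = 0.0432, 0.140 with an estimated correlation), with Nefl, the light neurofilament, at -2.95.

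In C57BL/6, 5961 genes were called at day 3 (3285 higher and 2676 lower than at day 0), 5244 at day 7 (2854 and 2390) and 4906 at day 14 (2482 and 2424) of 14545 tested. The split at day 14 turned with median centring (2287 and 2591), quantile normalization (2374 and 2568) and cyclic loess (2350 and 2607), as it did without C57BL/6 day 0 replicate 1 (1692 and 1712) or C57BL/6 day 14 replicate 2 (1767 and 1896). Of these, 2013, 1513 and 1325 changed at least 2-fold.

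The fourth question was what the crush did to the WldS nerve, whose axons survive longer. At day 3 macrophage, cell cycle and interferon response genes rose and myelin and cholesterol synthesis genes fell. Of 22 macrophage genes 21 rose (median 2.29, camera adjusted p = 3.23e-18), with Arg1 at 5.04 ± 0.39 and Fcgr1, an IgG receptor, at 4.21. Of 28 cell cycle genes 27 rose (median 2.23, adjusted p = 2.45e-23). Interferon response genes rose in 18 of 19 (median 1.74, adjusted p = 4.82e-13), led by the antiviral genes Mx1 (3.20) and Oas1a (3.05) and their regulator Irf7 (3.10). Slfn4 (6.08 ± 0.30), an interferon-inducible myeloid gene, and Ms4a4c (5.38 ± 0.26) rose most. Of 20 repair Schwann cell genes 6 rose and 8 fell (median -0.10, mean 0.17, test downward with adjusted p = 0.926). Of 19 myelin genes 15 fell (median -0.82, adjusted p = 3.18e-07, 0.121 with an estimated correlation), led by Gjc3 (-1.45) and Cmtm5 (-1.25). Cholesterol synthesis genes fell in 17 of 20 (median -1.75, adjusted p = 1.64e-14). Inmt fell most (-3.88 ± 0.27).

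Repair Schwann cell genes of WldS rose later. At day 7, 12 of 20 were higher and 1 lower (median 0.57, camera adjusted p = 0.0013, 0.0738 with an estimated correlation), and at day 14, 15 were higher and the others did not pass (median 0.98, adjusted p = 5.48e-11, 0.00486 with an estimated correlation). Shh was at 3.90 above day 0 on day 7 and 3.44 on day 14, Tnc at 3.97 on day 7, and Sox2 at 2.82 on day 14. Myelin genes were lower in 10 and higher in 3 of 19 at day 7 (median -0.41, adjusted p = 0.0013, 0.288 with an estimated correlation) and did not pass as a list at day 14 (median -0.15, adjusted p = 0.0855). Extracellular matrix genes rose in 25 of 28 at day 7 (median 0.95, adjusted p = 3.13e-12, 0.0738 with an estimated correlation), and Cthrc1, a collagen-modulating secreted protein, rose most at that day (5.39 ± 0.18). The mean level of the matrix list at WldS day 0, relative to C57BL/6 day 0, was lower in the high-index replicate 1 (-0.482) than in replicate 2 (-0.15). Endothelial genes rose in 8 of 15 at day 7 (camera adjusted p = 0.00245, 0.298 with an estimated correlation). Their mean level at day 0, relative to C57BL/6 day 0, was lower in the high-index replicate 1 (-0.422) than in replicate 2 (-0.176). At day 14, Wif1 (5.55 ± 0.14) and Rrm2 (4.71 ± 0.14) were highest, macrophage genes were higher in 14 and lower in 1 of 22 (adjusted p = 6.98e-09, 0.140 with an estimated correlation), and cholesterol synthesis genes were lower in 17 of 20 (median -1.75). Nefl fell most at day 14 (-2.81 ± 0.20), to 5.16 ± 0.23 from 7.96 ± 0.48. Of 10 skeletal muscle genes, which adjoining tissue can bring in, 7 were lower at day 14 (adjusted p = 0.000169, 0.203 with an estimated correlation).

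In WldS, 5236 genes were called at day 3 (3031 higher and 2205 lower), 5122 at day 7 (3188 and 1934) and 3094 at day 14 (1849 and 1245). The count was 3316 at day 3 without WldS day 3 replicate 1, and 1767 at day 14 without WldS day 14 replicate 1. With the 3'/5' index as a covariate it was 3465 at day 3 and 3337 at day 7, and with quantile normalization the split was 2660 higher and 2729 lower at day 3, which turned it, and 2690 and 2494 at day 7.

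**Figure D3:**
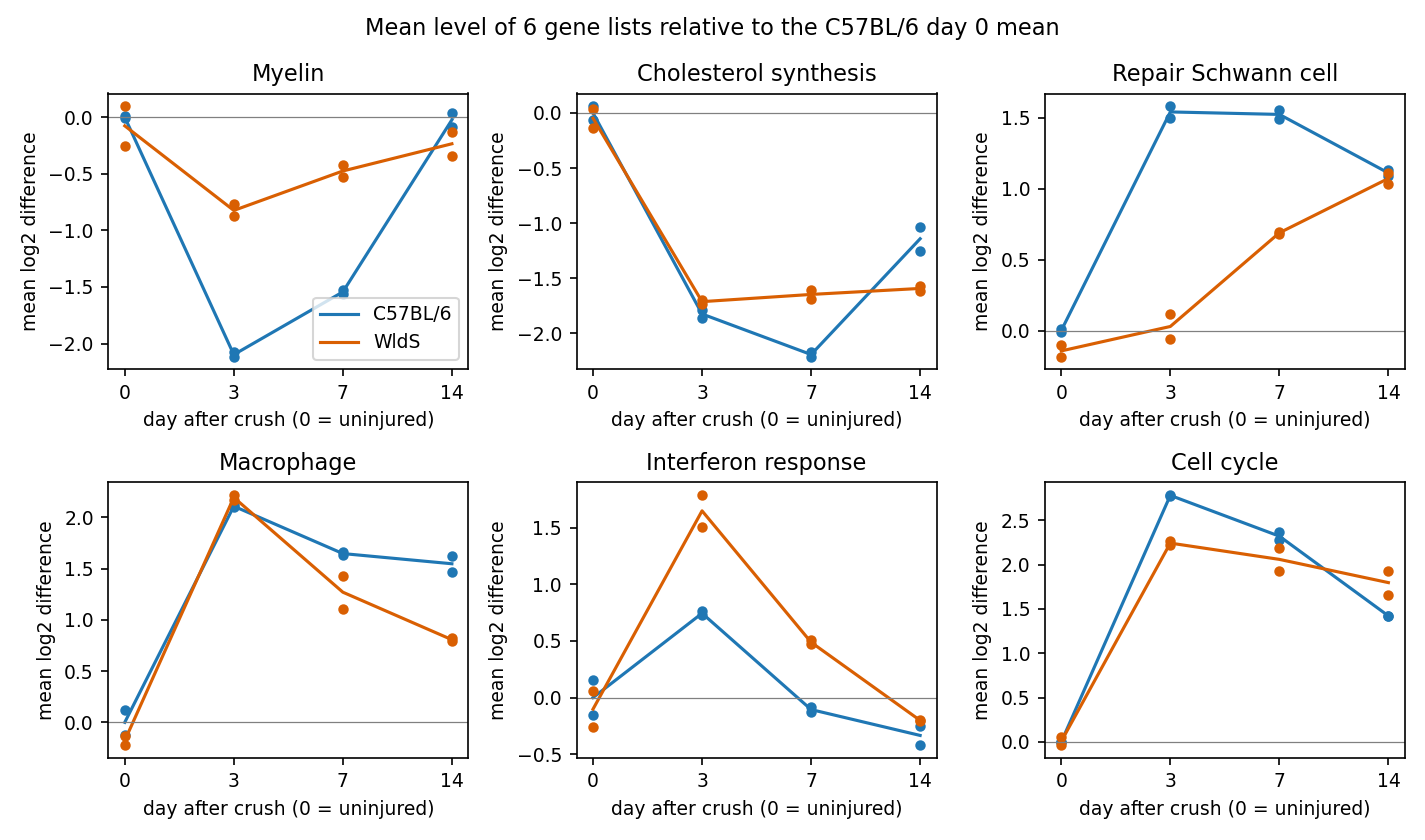
Points are arrays and lines group means of the mean log2 difference of a list's genes from the C57BL/6 day 0 mean, against day after crush, for 6 lists in C57BL/6 (blue) and WldS (orange). Repair Schwann cell genes had risen at day 3 in C57BL/6 (median 1.29) and not in WldS (median -0.10).

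The fifth question was where the injured nerves of the strains differed. At day 3 the WldS nerve had higher myelin and interferon response genes and lower repair Schwann cell genes than the C57BL/6 nerve. Of 20 repair Schwann cell genes 14 were lower and the others did not pass (median -1.33, camera adjusted p = 6.85e-24, 0.000328 with an estimated correlation), and 15 were lower adjusted over the list alone. Gdnf was lower by -4.45 ± 0.17 (5.65 against 10.10), Sox2 by -3.82 ± 0.13, Ngfr, the p75 neurotrophin receptor, by -3.66 and Btc by -3.63. Of 19 myelin genes 14 were higher and 2 lower (median 1.41, adjusted p = 3.78e-14, 0.0541 with an estimated correlation), with Ncmap higher by 4.60 ± 0.20 and Fa2h by 3.87 ± 0.11. Of 19 interferon response genes 14 were higher, and 18 adjusted over the list alone (median 0.94, adjusted p = 6.61e-16, 0.0541 with an estimated correlation), with Mx1 at 1.65 and Ifit3 at 1.27. Of 28 cell cycle genes 14 were lower, and 23 adjusted over the list alone (median -0.54, adjusted p = 1.07e-13, 0.0890 with an estimated correlation). Of 9 mast cell genes 5 were higher, among them the proteases Cpa3 (1.87) and Cma1 (1.59) (adjusted p = 8.42e-06, 0.0541 with an estimated correlation). Neurotrophic factor genes were lower in 5 and higher in 1 of 17 (adjusted p = 0.000481, 0.0541 with an estimated correlation), with Clcf1 at -3.56 and Fgf5 at -3.26. Macrophage genes did not pass (1 lower of 22, median 0.14, adjusted p = 0.220).

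At day 7 repair Schwann cell and phagocytosis genes were lower and myelin genes higher in WldS. Of 20 repair Schwann cell genes 12 were lower and 1 higher (median -0.83, camera adjusted p = 7.09e-15, 0.00187 with an estimated correlation). Of 19 myelin genes 13 were higher and 2 lower (median 1.24, adjusted p = 7.64e-15, 0.0386 with an estimated correlation), with Drp2, a dystrophin-related protein of the Schwann cell membrane, higher by 3.29 ± 0.13. Phagocytosis and lysosome genes were lower in 11 of 23 (median -0.60, adjusted p = 2.02e-10, 0.0370 with an estimated correlation), cholesterol synthesis genes higher in 7 of 20 (median 0.52, adjusted p = 5.98e-09, 0.0386) and pericyte and smooth muscle genes higher in 6 of 11 (median 0.61, adjusted p = 4.87e-07, 0.0386), the last p of each being with an estimated correlation. Clca3a2 was lower by -5.16 ± 0.24 and Tyrp1, a melanosomal enzyme, by -4.07 ± 0.16 (4.96 against 9.03). Macrophage genes were lower in 6 and higher in 2 of 22 (adjusted p = 0.0001, 0.299 with an estimated correlation).

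At day 14 the genes lowest in WldS relative to C57BL/6 were Chil3, Bex1, Arg1, Rnase2a and Fgf5. Chil3 was lower in WldS by -5.83 ± 0.20 (5.18 against 11.01), Arg1 by -3.65 ± 0.39 and Rnase2a, an eosinophil-type ribonuclease, by -3.43 ± 0.36. Of 22 macrophage genes 11 were lower and 1, Cd163, higher (median -0.59, camera adjusted p = 1.31e-09, 0.154 with an estimated correlation), and of 23 phagocytosis and lysosome genes 13 were lower (median -0.70, adjusted p = 1.95e-10, 0.0641 with an estimated correlation), led by Atp6v0d2 (-2.74). Bex1 was lower by -4.09 ± 0.33 and Fgf5 by -2.94 ± 0.15. Nmnat1 (3.40) and Mageb16 (at least 3.15 ± 0.20) were highest in WldS, and Crabp2, a retinoic acid carrier, was higher by 2.38 ± 0.23. MHC class II genes were lower in 4 of 11 (adjusted p = 0.00224, 0.258 with an estimated correlation).

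At day 3, 1373 genes differed between the strains (701 higher and 672 lower in WldS), at day 7, 994 (562 and 432) and at day 14, 939 (422 and 517). Leaving out single arrays left 897 (C57BL/6 day 3 replicate 1), 910 (C57BL/6 day 3 replicate 2), 723 (WldS day 3 replicate 1) and 803 (WldS day 3 replicate 2) at day 3. It left 522 (C57BL/6 day 7 replicate 1), 427 (C57BL/6 day 7 replicate 2) and 646 (WldS day 7 replicate 2) at day 7, and 344 (C57BL/6 day 14 replicate 1), 374 (C57BL/6 day 14 replicate 2) and 414 (WldS day 14 replicate 2) at day 14. Without both high-index arrays 563 genes differed at day 14, 287 higher and 276 lower. The splits at day 3 and 14 turned with normalization. At day 3 it was 639 higher and 690 lower with median centring and 814 and 599 with cyclic loess, and at day 14 it was 528 and 433 with quantile normalization. With the 3'/5' index as a covariate it was 486 and 469 at day 14, and without C57BL/6 day 14 replicate 2 it was 193 and 181.

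**Figure D4:**
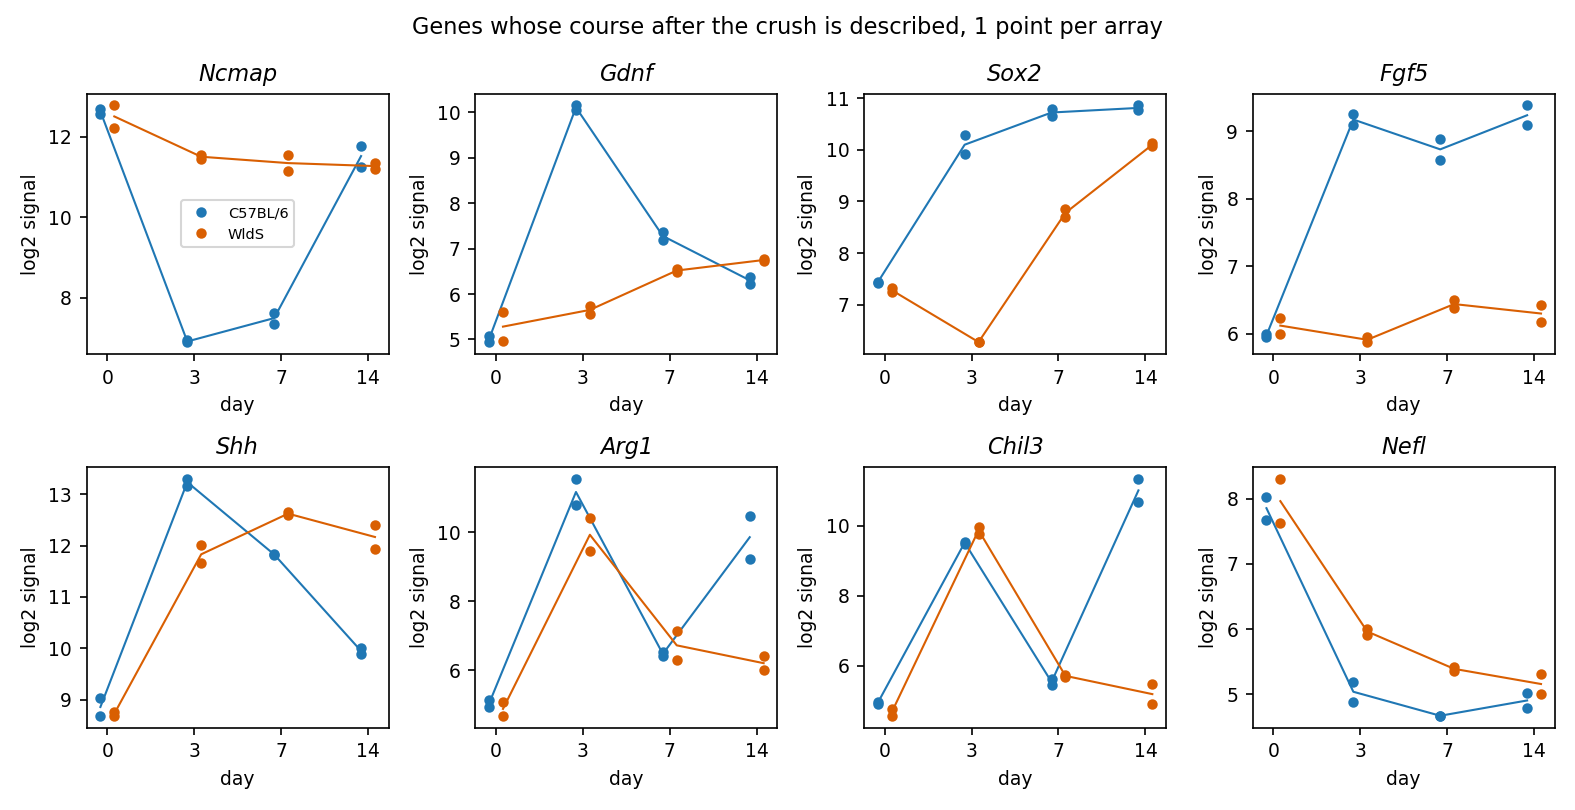
Points are arrays and lines group means (log2 signal against day after crush) for 8 genes in C57BL/6 (blue) and WldS (orange). Gdnf reached 10.10 at day 3 in C57BL/6 and 5.65 in WldS, and Chil3 stood at 11.01 and 5.18 at day 14.

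The sixth question was whether the change after injury itself differed between the strains. At day 3 the interaction was positive, meaning a smaller fall or larger rise in WldS, for 14 of 19 myelin genes and negative for 2 (median 1.53, camera adjusted p = 4.95e-12, 0.133 with an estimated correlation), with Ncmap at 4.72 ± 0.28 and Fa2h at 3.85 ± 0.15. It was negative for 11 of 20 repair Schwann cell genes (median -0.98, adjusted p = 2.06e-16, 0.00131 with an estimated correlation), with Gdnf at -4.73 ± 0.23, Btc at -3.70 ± 0.29 and Sox2 at -3.67 ± 0.18. It was positive for 10 of 19 interferon response genes, and for 16 adjusted over the list alone (median 0.99, adjusted p = 4.95e-12, 0.133 with an estimated correlation), and negative for 7 of 28 cell cycle genes (median -0.66, adjusted p = 2.19e-10, 0.133 with an estimated correlation). The neuronal vesicle protein gene Syt4 (-4.16 ± 0.21) and the chromatin protein gene Hmga2 (-4.07 ± 0.17) were among the lowest.

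At day 7 the interaction was positive for 11 and negative for 1 of 19 myelin genes (median 1.15, camera adjusted p = 1.34e-11, 0.114 with an estimated correlation), negative for 7 and positive for 1 of 20 repair Schwann cell genes (median -0.60, adjusted p = 8.99e-09, 0.0139 with an estimated correlation), and positive for 6 of 15 endothelial genes (median 0.84, adjusted p = 8.99e-09, 0.123 with an estimated correlation) and 3 of 19 interferon response genes (median 0.64, adjusted p = 6.93e-07, 0.190 with an estimated correlation). The WldS day 0 level of the endothelial list, relative to C57BL/6 day 0, was lower in the high-index replicate 1 (-0.422) than in replicate 2 (-0.176). Fam107a (5.65 ± 0.36) and Clca3a2 (-4.87 ± 0.33) were the extremes of the interaction at day 7. At day 14 it was negative for 4 and positive for 1 of 22 macrophage genes (median -0.57, adjusted p = 4.23e-07, 0.215 with an estimated correlation) and positive for 3 of 16 fibroblast and perineurial genes (median 0.76, adjusted p = 1.1e-08, 0.0752 with an estimated correlation). Myelin genes had a negative median at day 14 (-0.17, adjusted p = 0.0399, 0.476 with an estimated correlation), and that call ended without C57BL/6 day 0 replicate 2 (0.104), C57BL/6 day 14 replicate 2 (0.179), WldS day 0 replicate 2 (0.645) or WldS day 14 replicate 2 (0.277). Chil3 (-5.56 ± 0.29), Bex1 (-5.00 ± 0.46) and Arg1 (-3.49 ± 0.56) were lowest, and Cnmd, a chondromodulin (3.13 ± 0.49), and Shh (2.35 ± 0.23) were among the highest. Shh fell back to 9.95 in C57BL/6 by day 14 and was at 12.17 in WldS. The Arg1 call ended without C57BL/6 day 0 replicate 1 (adjusted p = 0.0540).

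The interaction passed for 896 genes at day 3 (584 positive and 312 negative), 598 at day 7 (420 and 178) and 230 at day 14 (132 and 98). Single arrays moved these counts. At day 3 they were 524 without C57BL/6 day 0 replicate 1, 527 without C57BL/6 day 3 replicate 1, 575 without WldS day 0 replicate 1, 2058 without WldS day 0 replicate 2, 460 without WldS day 3 replicate 1 and 555 without WldS day 3 replicate 2. At day 7 they were 302 and 369 without C57BL/6 day 0 replicate 1 and 2, 287 and 235 without C57BL/6 day 7 replicate 1 and 2, 362 and 1647 without WldS day 0 replicate 1 and 2, and 396 without WldS day 7 replicate 2. At day 14 they were 57 and 150 without C57BL/6 day 0 replicate 1 and 2, 81 and 99 without C57BL/6 day 14 replicate 1 and 2, 525 without WldS day 0 replicate 2 and 61 without WldS day 14 replicate 1. Without both high-index arrays the count at day 14 was 139, and with the index as a covariate 375. The split at day 14 was 28 positive and 29 negative without C57BL/6 day 0 replicate 1 and 35 and 46 without C57BL/6 day 14 replicate 1.

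**Figure D5:**
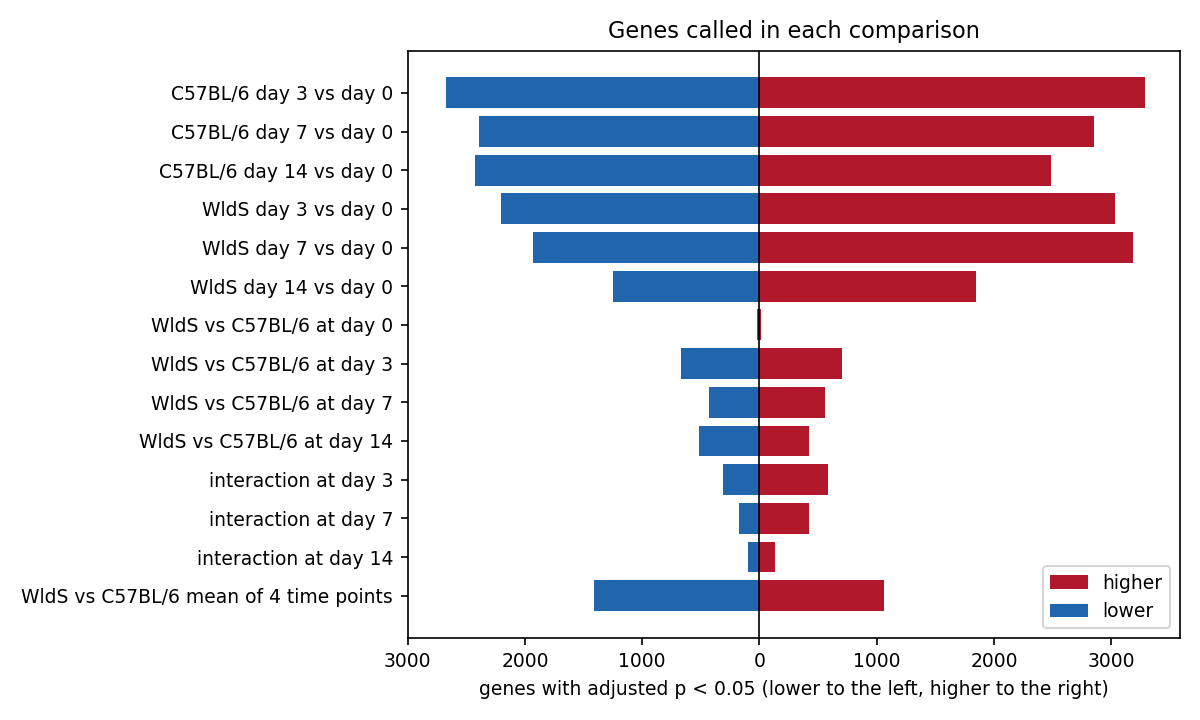
Bars give the number of genes called in each comparison at adjusted p below 0.05, lower to the left and higher to the right. Injury against day 0 gave between 3094 and 5961 genes and the strains at day 0 differed in 33.

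The responses of the strains overlapped in direction. At day 3, 2223 genes were higher in both strains, where independent lists would share 684.6, and 1533 were lower in both (405.7 for independent lists). At day 7 these were 2063 (625.5) and 1269 (317.8), and at day 14, 1427 (315.5) and 1022 (207.5). Genes changed in both strains in the same direction at day 14 numbered 2449, and 1580 without WldS day 14 replicate 1. Of the C57BL/6 calls with an interaction, 267 of 325 higher and 470 of 476 lower genes at day 3 changed less in WldS, as did 161 of 190 and 314 of 314 at day 7, and 94 of 105 and 109 of 113 at day 14. A selection on the C57BL/6 change favours this outcome. Of the WldS calls with an interaction, 127 of 197 higher and 85 of 376 lower genes at day 3 changed less in C57BL/6, as did 129 of 210 and 26 of 184 at day 7, and 27 of 76 and 5 of 60 at day 14. Lower genes with an interaction thus fell less in WldS in both tallies, and for higher genes the majority at day 3 and 7 depended on the strain used for selection. Across genes, the WldS change at day 3 correlated with the C57BL/6 change at day 3 at r = 0.802 and at day 14 at 0.580. The WldS change at day 7 correlated with that of C57BL/6 at day 3, 7 and 14 at 0.719, 0.793 and 0.681. The WldS change at day 14 correlated with that of C57BL/6 at day 7 at 0.863 and at day 14 at 0.834. The spread of these values between single arrays had a standard deviation of 0.052 to 0.097, so the last difference was smaller than that spread.

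The seventh question was how the strains differed over the mean of the 4 time points, which does not require a difference at each. Over this mean Clca3a2 (-2.52 ± 0.12), Fgf5 (-2.09 ± 0.07), Epha5 (-1.74 ± 0.08) and Sox2 (-1.66 ± 0.06) were lower in WldS, and Nmnat1 (3.05 ± 0.08), Jchain (2.82 ± 0.25), Fam107a (2.81 ± 0.13), Mageb16 (at least 2.71 ± 0.10) and Igkv8-30 (2.07 ± 0.19) were higher. Clca3a2 (-0.29), Fgf5 (0.15), Epha5 (-0.28), Sox2 (-0.15) and Fam107a (0.23) did not pass at day 0, whereas Nmnat1, Jchain, Mageb16 and Igkv8-30 passed at each time point. The day 0 calls of Jchain and Igkv8-30 ended without single arrays, as given above, and the Jchain call at day 14 ended without C57BL/6 day 14 replicate 1 (adjusted p = 0.0540) or replicate 2 (0.0603). Of 9 mast cell genes 8 were higher (median 0.54, camera adjusted p = 4.56e-07, 0.0335 with an estimated correlation), with the proteases Cpa3 (1.08), Cma1 (1.06) and Mcpt4 (0.70) first. Of 20 repair Schwann cell genes 14 were lower and 1 higher (median -0.68, adjusted p = 2.18e-11, 0.00479 with an estimated correlation), and of 23 phagocytosis and lysosome genes 17 were lower and 1 higher (median -0.35, adjusted p = 1.58e-09, 0.0335 with an estimated correlation). Interferon response genes were higher in 12 of 19 (adjusted p = 4.36e-09, 0.119 with an estimated correlation) and myelin genes higher in 12 and lower in 2 of 19 (adjusted p = 4.47e-09, 0.119 with an estimated correlation). Repair Schwann cell genes did not pass at day 0 (adjusted p = 0.206) or day 14 (adjusted p = 0.971), and myelin genes did not pass at day 0 (adjusted p = 0.848) and were lower at day 14 (median -0.26, adjusted p = 0.0154, 0.578 with an estimated correlation), a call that ended without C57BL/6 day 14 replicate 2 (median -0.21, 0.105) or WldS day 14 replicate 2 (-0.15, 0.0974). It also ended without both high-index arrays (-0.15, 0.0789) and with the 3'/5' index as a covariate (-0.13, 0.107), so this difference moved with RNA quality. In all 2479 genes differed, 1065 higher and 1414 lower in WldS, and 75 of them by at least 2-fold. With quantile normalization the split was 1271 higher and 1111 lower, and with the 3'/5' index as a covariate 1018 and 1001.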

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

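The tests of RNA degradation and of a later response in this part were chosen after the results were seen.

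The strains differed in their change after injury, by the test of the interaction itself, for 896 genes at day 3, 598 at day 7 and 230 at day 14. At day 3 the extremes were Ncmap (4.72) and Gdnf (-4.73), Pttg1 stood at 3.00, and the list medians were 1.53 for myelin, -0.98 for repair Schwann cell, 0.99 for interferon response and -0.66 for cell cycle genes (adjusted p with an estimated correlation 0.133, 0.00131, 0.133 and 0.133). At day 7 the extremes were Fam107a (5.65) and Clca3a2 (-4.87), Pttg1 stood at 2.41, and the medians were 1.15 for myelin, -0.60 for repair Schwann cell, 0.64 for interferon response and 0.84 for endothelial genes (0.114, 0.0139, 0.190 and 0.123). At day 14 the extremes were Cnmd (3.13) and Chil3 (-5.56), Pttg1 stood at 2.14, and the medians were -0.57 for macrophage and 0.76 for fibroblast and perineurial genes (0.215 and 0.0752). With that correlation only the repair Schwann cell calls among these held.

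The 3'/5' index of the control probe sets, which the comparisons of genes do not use, was 3.81 in WldS day 0 replicate 1 and 3.23 in WldS day 14 replicate 2, above both uninjured C57BL/6 arrays. Across genes, which are not independent replicates, the difference between the high-index array and its partner correlated between day 0 and day 14 of WldS at 0.582, against at most 0.418 in size for the other 27 pairs of groups. A shared degradation of RNA in these 2 pools may account for what sets them apart from their partners. A shared difference in tissue composition was not tested.

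Whether degradation was the whole cause of the interactions could not be decided by the values without these 2 arrays. The called genes then had a median of 0.91 of their interaction at day 3, 0.92 at day 7 and 1 at day 14. These genes had been called with both arrays in the fit, where a shift in 1 array alone also raises the spread. Such a shift was unlikely to be called, so medians near 1 were favoured in advance. RNA degradation in 2 WldS arrays may still account for part of the interactions. The strain, which the design names, stays open as a biological explanation, and husbandry or dissection that differed between the strains was not tested.

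A response in WldS that is the same but later, within 14 days, may account for part of these genes. Of 267 genes that rose in C57BL/6 at day 3 and rose less in WldS, 34 had reached at least 0.5 of the C57BL/6 day 3 change in WldS at day 3 and 37.1% reached it at day 7 or 14 (64.8% in C57BL/6 itself), and the WldS share grew after day 3 by 0.44 of the growth that reaches the later C57BL/6 share (0.41 to 0.51 leaving out 1 array). Of the 112 among them that kept at least 0.5 of the change in C57BL/6 at both later days, 72.3% reached it in WldS (65.2% to 76.8% leaving out 1 array) with 0.37 of that growth (0.34 to 0.42), so a later response stays open for the genes that rose. Of 470 genes that fell and fell less in WldS, 64 had reached it at day 3 and 98, or 20.9%, at day 7 or 14 (68 without WldS day 0 replicate 2 and 164, or 34.9%, without replicate 1, against 81.7% in C57BL/6 itself), and their median WldS share of 0.30, 0.25 and 0.28 at day 3, 7 and 14 gave 0.01 of that growth (-0.06 to 0.09). This argues against a later response within 14 days for the 470 genes that fell, as a set and not for each gene. For the 238 among them that lasted in C57BL/6 the part was 0.16 (0.12 to 0.25). Of these 238, 38.7% reached 0.5 of the change, or 58.4% without WldS day 0 replicate 1. Their median WldS share was 0.31, 0.32 and 0.42 at day 3, 7 and 14. The share of genes reaching 0.5 moved with 1 array and does not decide the question alone. The growth stayed small whichever array was left out, which argues against a later response within 14 days for these 238 too, as a set and not for each gene.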

How the results depend on the processing

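The alternatives that leave out the 2 arrays with a high 3'/5' index or use that index as a covariate were chosen after seeing the data. Called named genes and lists kept their direction under the alternatives run except for 4 values. With the mean of all probe sets these were Nampt at day 3 in WldS (0.18) and Uty at day 3 and 7 in WldS (0.42 and 0.55). With the index as covariate it was Atp5b at day 7 in WldS (-0.004). The cause was not tested. Some alternatives could not turn a gene's direction. The 2-fold threshold, the trend and robust setting, the replicate block and the restriction to the arrays compared leave its estimate as it is. With every probe set tested singly, a named gene was followed by its same probe set. With an estimated correlation 137 list results lost their call. The 406 list results run include those not called with the preset correlation, so the share lost among the calls was larger than 137 of 406.

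Counts are given in the order C57BL/6 day 3, 7 and 14, WldS day 3, 7 and 14, strains at day 0, 3, 7 and 14, where all moved. With a 2-fold threshold, which is stricter by construction, they were 2013, 1513, 1325, 1437, 1216, 694, 16, 393, 291 and 195, with 496 and 350 for the interaction at day 3 and 7 and 75 for the mean of the time points. With every probe set tested singly, which tests more features, they were 11525, 9783, 9329, 10288, 9951, 5430, 81, 2196, 1528 and 1535, with 4326 for the mean. With only the arrays compared, which has fewer degrees of freedom, WldS day 7 gave 2264, WldS day 14 1097, the strains at day 0 10 and the interactions 548, 301 and 90. Without the 2 high-index arrays the strains at day 14 gave 563 and the interaction at day 14 139. With the index as a covariate WldS day 3 gave 3465, WldS day 7 3337, the strains at day 0 15 and the interaction at day 14 375. The strains at day 0 gave 21 with cyclic loess and 19 with the replicate number as a block, and the cause was not tested. The replicate numbers did not pair the arrays, since only 5 of 28 pairs of groups had a correlation of replicate differences above 0.1 (median 0.006).

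Leaving out 1 array at a time, with the lone array assumed to vary like the other groups, gave 4476 to 5260, 3585 to 4274 and 3316 to 3965 genes for C57BL/6, 3316 to 5244, 3993 to 5067 and 1767 to 2900 for WldS, 7 to 1791, 723 to 910, 427 to 1082 and 344 to 840 for the strains, 460 to 2058, 235 to 1647 and 57 to 525 for the interactions, 1657 to 3429 for the mean of the time points, and 2754 to 3600, 2491 to 3156 and 1580 to 2348 for genes changed alike in both strains. Counts under the other alternatives stayed within 1.5 times. With cyclic loess the strain mean split into 1236 higher and 1121 lower. Arrays do not resolve genes near background, where a change is compressed, as for Cd79a, Ms4a1, Pax5 and Mmrn1 in C57BL/6.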

Other observations

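The tests of cell sources, with the reasons that leave them open, and of RNA degradation in this part were chosen after the results were seen, and the shuffling of strain labels was planned.

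Toll-like receptor signalling genes rose in 10 of 20 at day 3 in C57BL/6 (camera adjusted p = 0.00261, 0.101 with an estimated correlation) and in 13 of 20 in WldS (adjusted p = 5.86e-06, 0.0240 with an estimated correlation), led in both by Tlr1 (3.67 and 3.48). Complement genes passed in WldS at day 3 (7 higher and 2 lower of 15, adjusted p = 0.0226, 0.248 with an estimated correlation) and not in C57BL/6 (8 higher and 6 lower, adjusted p = 0.729), and their interaction passed (4 higher, median 0.68, adjusted p = 0.00152, 0.133 with an estimated correlation). Cell cycle genes, lower in WldS at day 3, were higher in WldS at day 14 in 4 of 28 (median 0.36, adjusted p = 2.85e-07, 0.258 with an estimated correlation), with Rrm2 at 0.96.

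NAD metabolism genes, a group to which Nmnat1 belongs, did not pass between the strains over the mean of the time points (4 of 19 higher, median 0.07, camera adjusted p = 0.0720). T and B lymphocyte genes did not pass there either (1 of 9 lower, adjusted p = 0.662), nor did neutrophil genes (2 higher and 2 lower of 13, adjusted p = 0.830) or genes of axon growth inhibition and guidance (3 higher and 4 lower of 25, adjusted p = 0.485). Adipocyte genes fell in both strains at day 7, in 10 of 11 in C57BL/6 (median -1.94, adjusted p = 1.13e-06, 0.221 with an estimated correlation) and in 9 of 11 in WldS (median -1.01, adjusted p = 0.000321, 0.288 with an estimated correlation).

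For the 2479 genes that differed over the mean of the time points, 1 of 100 splits with strain labels shuffled within time points, the real one, gave as many. This is the smallest share that 100 splits can give. The highest of the others gave 1842 and their median was 1. This argues against chance as the source of so high a count of genes, and it does not test each of the 2479. Without the 2 high-index arrays these genes had a median of 0.94 of their difference, and all 2479 kept their direction. They had been called with both arrays in the fit, where a shift in these arrays alone also raises the spread. A ratio near 1 was thus favoured in advance and does not decide whether degradation was the whole cause.

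More antibody-secreting cells in the WldS nerves could account for the higher Jchain, Ighm and Igkv8-30. Of 9 plasma cell markers without immunoglobulin genes, 1 was higher (Mzb1, 0.35) and 1 lower (Prdm1, -0.23), with a median of -0.07 over the mean of the time points. As a list they had an unadjusted p = 0.99 with limma's camera. The hypothesis stays open, since Mzb1 moved with it and the nerve itself expressed other markers, such as Sdc1 (9.01 in C57BL/6), at a level that would hide a small share of cells. More B cells were tested by 5 markers, with a median of 0.07 and upper 95% bounds of at most 0.40. The smallest of the immunoglobulin differences was 1.82, for Ighm at its brightest probe set. The next brightest Ighm probe set differed by 1.03 and the others by 0.26 or less. More B cells stay open because Cd79a, Ms4a1 and Pax5 lay near the dim filter.

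More lymphatic vessel tissue might account for the higher Mmrn1 in WldS. Of 4 lymphatic vessel markers the median difference was -0.11, with a median upper 95% bound of 0.09 against 1.01, which is 0.5 of the Mmrn1 difference, and Lyve1 was lower (-0.37). It stays open because Reln (12.29 in C57BL/6) and Pdpn (10.75) stood at levels that would hide a small share. Flt4, at a lower level (7.16), did not rise (-0.14 ± 0.10, upper 95% bound 0.08). A difference in the Mmrn1 gene itself between the stocks was not tested.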
